A study of Mus musculus with 6 samples.

How the data were processed

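Total RNA of splenocytes was extracted on silica columns with DNase digestion and profiled with version 1.5 of the nCounter mouse miRNA panel by the manufacturer, per the labels. The deposited values are whole-number scores per probe and sample that behave as normalized counts. How the authors normalized them, corrected for background or rounded is not given in the sources used here, so what follows on normalization was read from the values. No value was under 1. The geometric mean of the 100 highest miRNAs agreed within 1.50% across samples while the summed positive controls differed by 30.6%. Low whole numbers were unevenly filled, as after scaling and rounding. In EE sample 2, 3 probes stood at 10, against 21 at 9 and 22 at 11. The scores were therefore treated as counts rescaled per sample, close to a top-100 normalization, and no count model was fitted. Such a scaling fixes the mean level of the abundant miRNAs, so a rise in some of them lowers the others. The raw depth per sample is unknown, and intervals for counting error were not computed.

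The table held 626 probes, of which 566 named mouse miRNAs, 33 viral miRNAs, 6 positive and 8 negative controls, 4 housekeeping mRNAs, 3 non-mammalian spike-ins and 6 ligation controls. All 6 sample columns were used. Probes were kept by their names as listed, some of which name several miRNAs. Of the 95 tested probes, 76 matched a miRNA gene name in the RefSeq gene table of mouse given for this work, which was used for names and neighbours alone; the table names an assembly, but the probes carry no genome build, so no coordinates are printed. Several unmatched probes carry older names or come from loci with several copies. miR-2132 and miR-2141, named below, are also unmatched, so these names were not tied to a miRNA gene.

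The main test was limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes with a mean trend on log2(value + 1). Fold changes are on that scale, and the pseudocount understates changes of low probes. They compare means of log2 values, so they need not equal the ratio of the mean counts printed beside them. All 6 samples and 3 groups entered a single fit, which had 7.50 prior and 10.5 total degrees of freedom. Tested probes were mouse miRNAs with a mean over all samples above the mean + 2 SD of the 8 negative control probes, a floor of 53.3. Tests were two-sided, adjusted by the Benjamini-Hochberg method over 95 miRNAs, with a threshold of 0.05. The comparisons were E2 with placebo, EE with placebo, EE with E2, and both estrogens with placebo. An exact two-sided permutation test of 2 against 2 samples cannot give a p below 0.333, so none was run for single miRNAs, and groups of 2 allow no test for outlying samples. The groups, filter, lists and naming rule were fixed before the data were examined, as was the choice of limma for normalized values and of a count model for raw counts. Which of these applied was decided from the values.

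The naming rule took, per pairwise comparison, up to 10 miRNAs with the largest rise and 10 with the largest fall past the threshold. A direction with fewer than 10 was filled up to 10 with miRNAs of smallest unadjusted p under 0.05 whose samples did not overlap between groups, stated as not past the threshold. It also took every tested member of the lupus list and both earlier estrogen lists, and up to 4 members of each other list with the smallest unadjusted p. Lists were written from background knowledge. They covered miRNAs raised in lupus-prone mouse splenocytes, miRNAs reported as higher or lower in earlier estrogen studies, the Dlk1-Dio3 and Sfmbt2 clusters, the miR-17-92, let-7, miR-29, miR-30 and miR-15/16 families, NF-kB-linked inflammatory miRNAs, and markers of lymphoid, myeloid, erythroid, endothelial, stromal and smooth muscle, skeletal and cardiac muscle, pancreas, liver and epithelial cells. Lists with at least 3 tested members, 13 of 20, were tested with limma's camera at a preset correlation of 0.01, adjusted over 13 lists within a comparison, beside camera with an estimated correlation and fry. With an estimated correlation no list passed in any comparison.

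Correlations of the E2 and EE responses were set beside 1000 simulated draws of unchanged groups that shared the placebo samples, and the overlap of their calls beside 100 such draws fitted with limma. The fit was tested on simulated data for the comparison of E2 with placebo over 95 miRNAs in 50 draws with 20 changed miRNAs each. It recovered 86.2% of changes of 1 log2 unit and 97.4% of changes of 2 log2 units, 3.47% of its calls were false and 0 had the wrong sign. The simulated noise was independent between miRNAs, and rises and falls were equal in number. Errors of scaling and background and correlation between miRNAs were left out, so the false share need not hold for the real calls. Alternatives were rescaling by the 100 highest miRNAs or by the median tested miRNA, quantile normalization, a pseudocount of 10, no filter, a filter at 107 normalized counts, eBayes without trend or with a robust trend, a fit of the compared groups alone and leaving out each sample. Rescaling by the 4 housekeeping mRNAs or the 3 ligation positive controls was added after seeing the data. Plots were drawn with matplotlib 3.10.9.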

Results

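Splenocytes of female NZB/WF1 mice, a cross that develops a spontaneous disease resembling human systemic lupus erythematosus, were profiled for miRNAs after long exposure to an estrogen. The animals carried an implant with 17β-estradiol (E2, the natural hormone), an implant with 17α-ethinyl estradiol (EE, the synthetic estrogen of oral contraceptives, which differs from E2 by an ethinyl group at carbon position 17α) or an empty implant (placebo). Implants were placed at 6 to 7 weeks of age, and splenocytes were collected after 9 weeks of treatment. Each group held 2 samples, 6 in all, and miRNAs were counted with the nCounter assay, in which colour-coded barcodes are read from single molecules without amplification. The labels do not state that the 2 samples of a group came from separate mice, so p-values measure the spread between these samples. Implant doses are not given in the sources used here.

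The table held 566 mouse miRNA probes, and 95 of them had a mean above the detection floor of 53.3 normalized counts set from the negative control probes. A negative control probe itself stood above this floor, at 59 and 56 in the EE samples and 58 in placebo sample 1. Summed normalized counts over all probes ranged from 167152 in EE sample 1 to 205209 in placebo sample 1. These sums came after normalization, so they do not give the depth of the raw barcode counts, which is unknown. The lymphocyte miRNA miR-150 was the most abundant species in every sample. It made up 29.2% and 25.2% of all mouse miRNA counts in the placebo samples, 18.7% and 18.8% in the E2 samples and 13.5% and 12.7% in the EE samples. Samples of a group differed by a median absolute log2 difference of 0.18 in E2, 0.16 in EE and 0.22 in placebo across the 95 tested miRNAs. The largest differences within a group were those of miR-155 in EE, at 2.93 log2 units, and of miR-376a in E2, at 2.68. The first principal component held 67.2% of the variance and placed both placebo samples on the side opposite to all 4 estrogen samples.

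The comparison of E2 with placebo asked which splenic miRNAs changed with the natural hormone. The largest rises were in miR-486, miR-144 and miR-451, all highly expressed in developing red blood cells, and in miR-223, a miRNA of neutrophils and other myeloid cells. miR-486 went from 138 ± 77.1 normalized counts with placebo to 976.5 ± 4.95 with E2 (SD, n = 2 each), a 7.68-fold rise between the means of log2 values. miR-144 rose 6.39-fold, miR-451 rose 4.71-fold and miR-223 rose 3.09-fold, the last from 1110 ± 281 to 3383 ± 197 normalized counts (SD, n = 2 each). miRNAs of lymphocytes moved the opposite way. miR-150 fell from 39624 ± 6363 to 23444 ± 1084 normalized counts (SD, n = 2 each), and miR-181a and miR-342-3p fell with it.

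In limma's moderated test over 95 miRNAs, 4 were higher and 6 were lower with E2 at the threshold. The log2 fold changes were 2.94 ± 0.31 (SE) for miR-486, with an adjusted p of 1.13e-04, 2.68 ± 0.30 for miR-144, 2.24 ± 0.32 for miR-451, with an adjusted p of 7.38e-04, and 1.63 ± 0.18 for miR-223. The 6 lower miRNAs were miR-2132 (log2 fold change -0.99), miR-125b-5p (-0.97), miR-150 (-0.75, adjusted p 9.53e-04), miR-181a (-0.71), miR-142-3p (-0.60) and miR-342-3p (-0.50, adjusted p 0.0411). The E2 mean of miR-125b-5p, 37.5 normalized counts, lay under the detection floor, so the size of its fall is uncertain. So is the size of the miR-144 rise, with placebo samples near the floor at 73 and 45 normalized counts. All 10 had both E2 samples beyond both placebo samples, as did 60 of the 95 tested miRNAs, where chance gives 33.3%. At an unadjusted p under 0.05 the count was 20. The miRNAs named by the rule and not past the threshold had log2 fold changes of 0.75 (miR-2141), 0.68 (miR-1949), 0.65 (miR-148a), 0.61 (miR-709), 0.51 (miR-15a), 0.50 (miR-93), -0.39 (miR-191), -0.41 (miR-21), -0.45 (miR-30d) and -0.68 (miR-125a-5p). The median log2 fold change of all 95 was -0.20, so the fold changes stand on a slightly negative centre.

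The erythroid list had 3 tested members, and all 3 rose, both at the threshold over all tested miRNAs and adjusted over the list alone. Their median log2 fold change was 2.68, and camera gave the list an adjusted p of 1.75e-06, against an adjusted p of 0.258 with an estimated correlation. The list of miRNAs reported as higher in earlier estrogen studies, fixed from background knowledge, shares miR-451 and miR-486 with the erythroid list. Of its 4 tested members 3 rose, and 4 did so adjusted over the list alone (camera adjusted p 8.66e-07, and an adjusted p of 0.258 with an estimated correlation). All 3 tested lymphoid markers fell, adjusted over all miRNAs and adjusted over the list alone, with a median of -0.71 (camera adjusted p 0.0189, and an adjusted p of 0.350 with an estimated correlation). The lymphoid median was -0.60 with median rescaling (camera adjusted p 0.0527) and -0.45 with quantile normalization (0.164), and neither passed. Quantile normalization removes the change of miR-150 by construction, since it ranked first in every sample. No member of the miR-17-92 family, a group linked to cell proliferation, passed over all miRNAs or adjusted over the list alone, while the family's 7 tested probes had a median of 0.33 (camera adjusted p 0.0384, and an adjusted p of 0.337 with an estimated correlation). The family's call ended in 5 of 6 fits that left out a sample, all but that without E2 sample 1, with adjusted p-values up to 0.246, and the lymphoid call ended without placebo sample 1 (adjusted p 0.0981). The myeloid list gave 1 rise among 4 members, that of miR-223, over all miRNAs and adjusted over the list alone. Its median was -0.14 and its mean 0.25, with a camera direction upward and an adjusted p of 0.419.

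The list of miRNAs reported as lower in earlier estrogen studies had 1 of 5 tested members lower with E2, miR-125b-5p, and 2 adjusted over the list alone. Its median was -0.39 (camera adjusted p 0.112, fry adjusted p 0.0118), with miR-146a at -0.31 and miR-145 at -0.39. The stromal and smooth muscle list had 1 of 3 tested members lower, again miR-125b-5p, also adjusted over the list alone (median -0.39, camera adjusted p 0.550, fry adjusted p 0.0444). No member passed, over all miRNAs or adjusted over the list alone, in the let-7 family (9 tested, median -0.19), the miR-30 family (5, -0.32), the miR-29 family (3, -0.30), the miR-15/16 family (4, 0.04), the inflammatory list of NF-kB-linked miRNAs (3, -0.41) or the Sfmbt2 intronic cluster (3, -0.44). Fry gave the Sfmbt2 cluster an adjusted p of 0.0444. Camera adjusted p-values of these 6 lists ran from 0.335 for the inflammatory and miR-30 lists to 0.655 for the let-7 family. Their direction held under every rescaling tried except that the let-7 and miR-29 medians turned positive with ligation controls, as did the myeloid median, and the miR-15/16 median turned negative with housekeeping mRNAs. The 3 erythroid rises carried a wide placebo spread, with miR-451 at 1128 and 468 normalized counts in the placebo samples, and a robust variance estimate ended the calls of miR-451 (adjusted p 0.116) and miR-486 (adjusted p 0.0522) with their fold changes unchanged. All 6 lower calls ended when samples were rescaled by their median tested miRNA or by ligation controls, and without the detection filter, while the 4 higher calls held in each of these settings. The fold changes of the 6 were unchanged without the filter and somewhat smaller with median rescaling (miR-2132 -0.88, miR-125b-5p -0.86, miR-150 -0.64, miR-181a -0.60, miR-142-3p -0.50, miR-342-3p -0.40), and smaller again with ligation controls, from -0.67 for miR-2132 to -0.18 for miR-342-3p. The count was 6 without E2 sample 1.

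**Figure D1:**
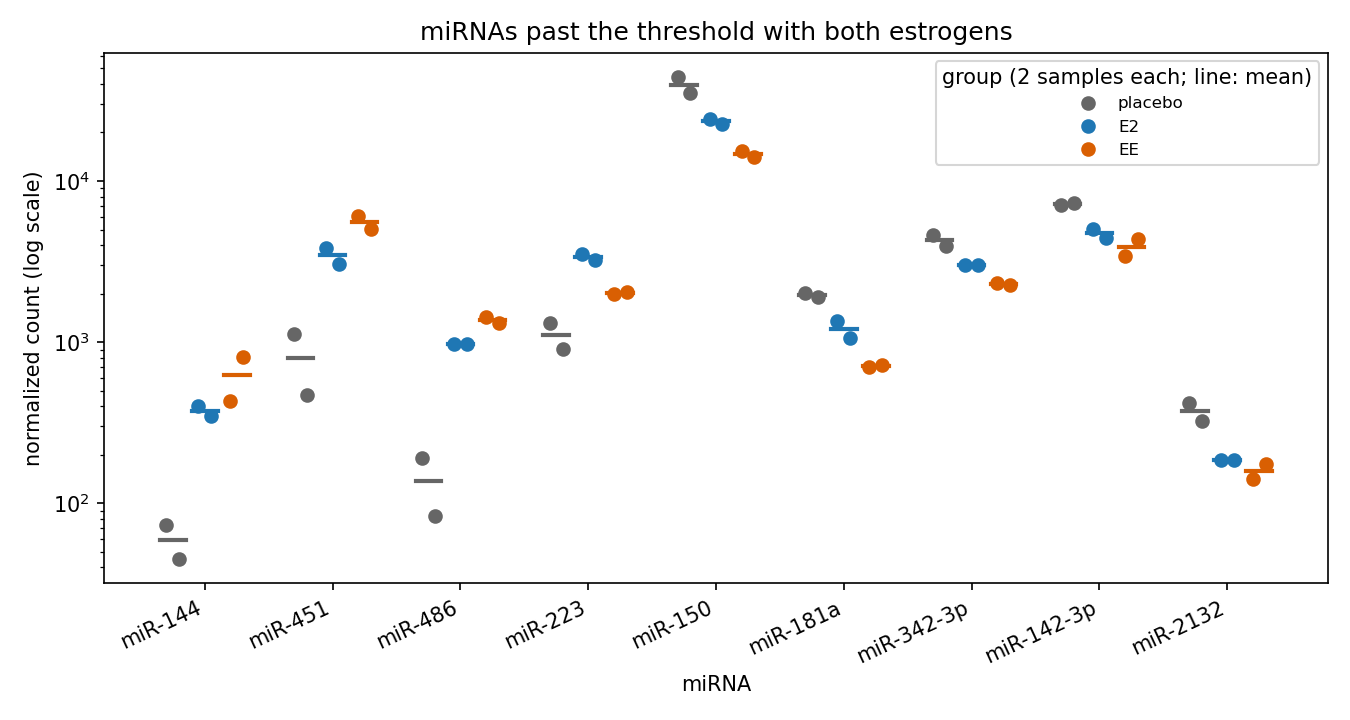
Normalized counts on a log axis of the 9 miRNAs past the threshold with both estrogens, with a point for each of the 2 samples per group and a line at the group mean. All E2 and EE points of miR-144, miR-451, miR-486 and miR-223 lie above both placebo points, and those of miR-150, miR-181a, miR-342-3p, miR-142-3p and miR-2132 lie below.

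The comparison of EE with placebo asked the same of the synthetic estrogen. The erythroid miRNAs again showed the largest rises. miR-486 rose 10.8-fold to 1378 ± 92.6 normalized counts, miR-144 rose 10.2-fold to 622 ± 272 and miR-451 rose 7.61-fold to 5560 ± 707 (SD, n = 2 each). The placebo samples of miR-144, at 73 and 45 normalized counts, lay near the detection floor, so the size of its rise is uncertain. miR-126-3p, an endothelial miRNA, rose 2.09-fold, miR-93 of the miR-17-92 family rose 1.92-fold and miR-223 rose 1.84-fold. Among lymphoid miRNAs, miR-150 fell to 14708 ± 804 and miR-181a to 708 ± 13.4 normalized counts (SD, n = 2 each), 2.68-fold and 2.76-fold below placebo. Of 33 panel probes for miRNAs encoded in an intron of Sfmbt2, the 3 with means above the detection floor also fell, and the rest were not tested. The combined probe for miR-466a-3p and miR-466b-3-3p was at 102.5 ± 21.9 normalized counts with placebo and 41.0 ± 1.41 with EE (SD, n = 2 each), the latter under the floor.

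With limma, 10 miRNAs were higher and 15 were lower with EE among 95. The higher miRNAs were miR-486 (log2 fold change 3.43 ± 0.31, SE, adjusted p 1.34e-05), miR-144 (3.35 ± 0.30), miR-451 (2.93 ± 0.32, adjusted p 6.36e-05), miR-126-3p (1.07 ± 0.19), miR-93 (0.94), miR-223 (0.88 ± 0.18, adjusted p 0.00424), miR-709 (0.75), miR-148a (0.69), miR-145 (0.63) and miR-15a (0.55, adjusted p 0.0433). The 10 largest falls were those of miR-181a (-1.47 ± 0.17, adjusted p 8.21e-05), miR-150 (-1.42 ± 0.11, adjusted p 1.18e-05), the miR-466a-3p and miR-466b-3-3p probe (-1.29), miR-2132 (-1.23), miR-669a (-1.13), miR-467f (-0.99), miR-342-3p (-0.90), miR-142-3p (-0.90), miR-1224 (-0.86) and miR-151-3p (-0.84). let-7g (-0.68), miR-30c (-0.62) and miR-23a (-0.62), a miRNA of myeloid cells, were among the other lower calls. The EE means of the miR-466a-3p and miR-466b-3-3p probe, miR-669a and miR-151-3p, at 41.0, 38.0 and 39.0 normalized counts, lay under the detection floor, so the sizes of these falls are uncertain. All 25 had both EE samples beyond both placebo samples, as did 60 of the 95. The median log2 fold change of all tested miRNAs was -0.11.

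All 3 erythroid markers rose with EE and all 3 tested lymphoid markers fell, over all miRNAs and adjusted over the list alone. Their medians were 3.35 (camera adjusted p 1.13e-04) and -1.42 (camera adjusted p 0.00181), and both lists had an adjusted p of 0.218 with an estimated correlation. With quantile normalization, which removes the change of miR-150 by construction, the lymphoid median was -0.68 and the list did not pass (camera adjusted p 0.110). The earlier estrogen list of higher miRNAs had 4 of 4 tested members higher, also adjusted over the list alone (camera adjusted p 2.05e-04, and an adjusted p of 0.218 with an estimated correlation). The 3 tested members of the Sfmbt2 cluster all fell, also adjusted over the list alone, with a median of -1.13 that includes 2 probes under the floor with EE (camera adjusted p 0.0302, and an adjusted p of 0.218 with an estimated correlation). In the miR-17-92 family 1 of 7 probes rose, miR-93, also adjusted over the list alone, with a family median of 0.42 (camera adjusted p 0.0121, and an adjusted p of 0.218 with an estimated correlation). The members miR-106b (0.46), miR-19a (0.45) and miR-25 (0.35) were not past the threshold. The Sfmbt2 call ended without EE sample 2 (adjusted p 0.0557), placebo sample 1 (0.115) or placebo sample 2 (0.0618), and the miR-17-92 call without EE sample 1 (0.0584) or 2 (0.0509).

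The stromal list had 1 of 3 members higher, miR-145, also adjusted over the list alone, with a median of 0.44 (camera adjusted p 0.189, fry adjusted p 0.0214). The EE call of miR-145 was lost in 9 of 16 alternatives, with log2 fold changes of 0.42 to 0.73. The myeloid list had miR-223 higher and miR-23a lower among 4 members, over all miRNAs and adjusted over the list alone, with a median of -0.09, a mean of 0.02, an upward camera direction (adjusted p 0.844) and a downward fry direction. The list of miRNAs reported as lower in earlier estrogen studies had none lower and miR-145 higher among 5, also adjusted over the list alone, with a median of -0.14, a mean of 0.05 and an upward camera direction (adjusted p 0.759). A single member passed in the let-7 family (let-7g lower of 9, median -0.17), the miR-30 family (miR-30c lower of 5, median -0.34) and the miR-15/16 family (miR-15a higher of 4, median 0.03), with the same counts adjusted over the list alone and camera adjusted p-values of 0.387, 0.459 and 0.754. None passed in either count in the miR-29 family (3, median -0.20, camera adjusted p 0.768) or the inflammatory list (3, median -0.35, camera adjusted p 0.754). The miR-15/16 median turned negative with ligation controls and the myeloid median positive with housekeeping mRNAs. The number of calls was 15 without EE sample 2 or after rescaling by the median tested miRNA, 14 without the detection filter, 16 with housekeeping mRNAs and 11 with ligation controls.

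E2 and EE shared 4 higher calls, miR-144, miR-223, miR-451 and miR-486, and 5 lower calls, miR-142-3p, miR-150, miR-181a, miR-2132 and miR-342-3p. Independent lists of these sizes would share 0.421 higher and 0.947 lower calls, a value that leaves out the shared placebo samples. Simulated unchanged groups against shared placebo samples had a mean of 0.06 higher and 0.03 lower calls in common, which leaves out real effects. The only E2 call outside the EE calls was miR-125b-5p, and no miRNA was called in opposite directions. Across the 95 miRNAs, which are not independent replicates, the log2 fold changes of E2 and EE had a Pearson r of 0.885 and a Spearman rho of 0.750. Both comparisons used the same 2 placebo samples, and simulated unchanged groups against shared placebo samples gave a mean r of 0.496 and rho of 0.473. All simulated groups had the same spread, whereas the real placebo samples differed most from each other, by a median of 0.22 log2 units. Shared placebo variation may therefore be understated in the draws. The covariance was 0.445 against 0.0254 in that simulation, and the 2 changes had the same sign for 82.1% of miRNAs against 66.7%. The placebo group was too small to split, so part of the excess may come from the shared samples. Without the erythroid markers and miR-223, a choice made after seeing the data, r was 0.738. With both estrogens pooled against placebo, 9 miRNAs were higher and 13 lower, a count that was 11 and 21 with a robust trend and 4 and 3 with ligation controls.

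**Figure D2:**
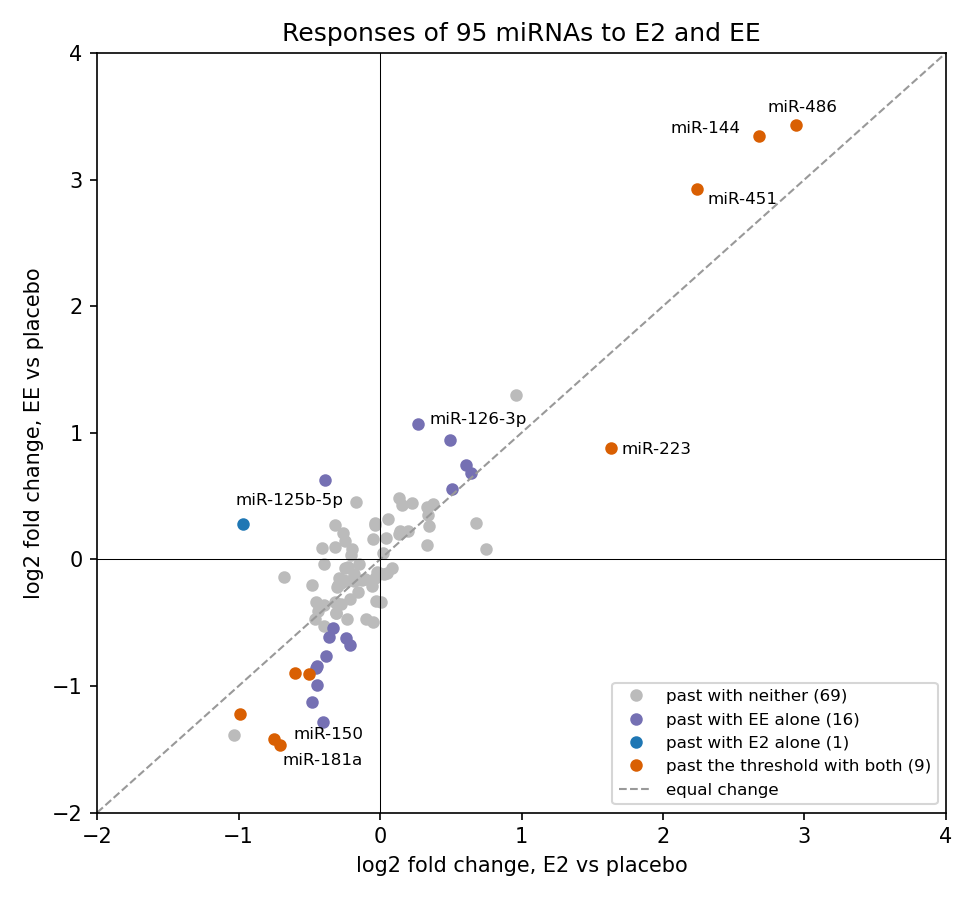
Log2 fold change with EE (vertical) against that with E2 (horizontal), both relative to placebo, for the 95 tested miRNAs, coloured by whether each passed the threshold, with a dashed line of equal change. The 3 erythroid miRNAs lie at the upper right above the line, miR-223 lies below it, and miR-125b-5p is the only point past the threshold with E2 alone.

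The direct comparison of EE with E2 asked where an estrogen with an added ethinyl group gave a different miRNA profile. The doses are not known to be matched, so the values stand side by side. miR-125b-5p and miR-145, miRNAs of stromal and smooth muscle cells, and the endothelial miR-126-3p were higher with EE. miR-145 was at 123 normalized counts in both EE samples against 60.5 ± 3.54 with E2 (SD, n = 2), and miR-125b-5p was at 89.0 ± 9.90 against 37.5 ± 10.6 (SD, n = 2 each). The lymphoid miRNAs miR-150 and miR-181a, the myeloid miR-223 and the probe for miR-466a-3p and miR-466b-3-3p were lower with EE. The E2 mean of miR-125b-5p and the EE mean of the miR-466a-3p and miR-466b-3-3p probe, 41.0 normalized counts, lay under the detection floor of 53.3, so the sizes of these differences are uncertain.

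With limma, 3 miRNAs were higher and 4 lower with EE among 95. The log2 differences were 1.25 ± 0.24 (SE) for miR-125b-5p and 1.01 ± 0.19 for miR-145, each with an adjusted p of 0.0121, and 0.80 ± 0.19 for miR-126-3p, with an adjusted p of 0.0320. They were -0.88 ± 0.22 for the miR-466a-3p and miR-466b-3-3p probe, -0.76 ± 0.17 for miR-181a, -0.75 ± 0.18 for miR-223 and -0.67 ± 0.11 for miR-150, the last with an adjusted p of 0.0117. All 7 had both EE samples beyond both E2 samples, as did 54 of the 95. The erythroid miRNAs did not pass. Their differences, with 95% confidence intervals, were 0.69 (-0.02 to 1.40) for miR-451, 0.67 (-0.00 to 1.34) for miR-144 and 0.49 (-0.19 to 1.18) for miR-486. miR-342-3p differed by -0.40 (-0.71 to -0.09), miR-142-3p by -0.29 (-0.62 to 0.04), miR-2132 by -0.23 (-0.67 to 0.20) and miR-148a by 0.04 (-0.42 to 0.51), none past the threshold. Also not past it were the differences named by the rule for miR-106b (0.62), miR-484 (0.59), miR-125a-5p (0.53), miR-21 (0.50), miR-103 (0.47), miR-93 (0.45), let-7g (-0.46), miR-467f (-0.55), miR-669a (-0.64) and miR-2141 (-0.67).

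**Figure D3:**
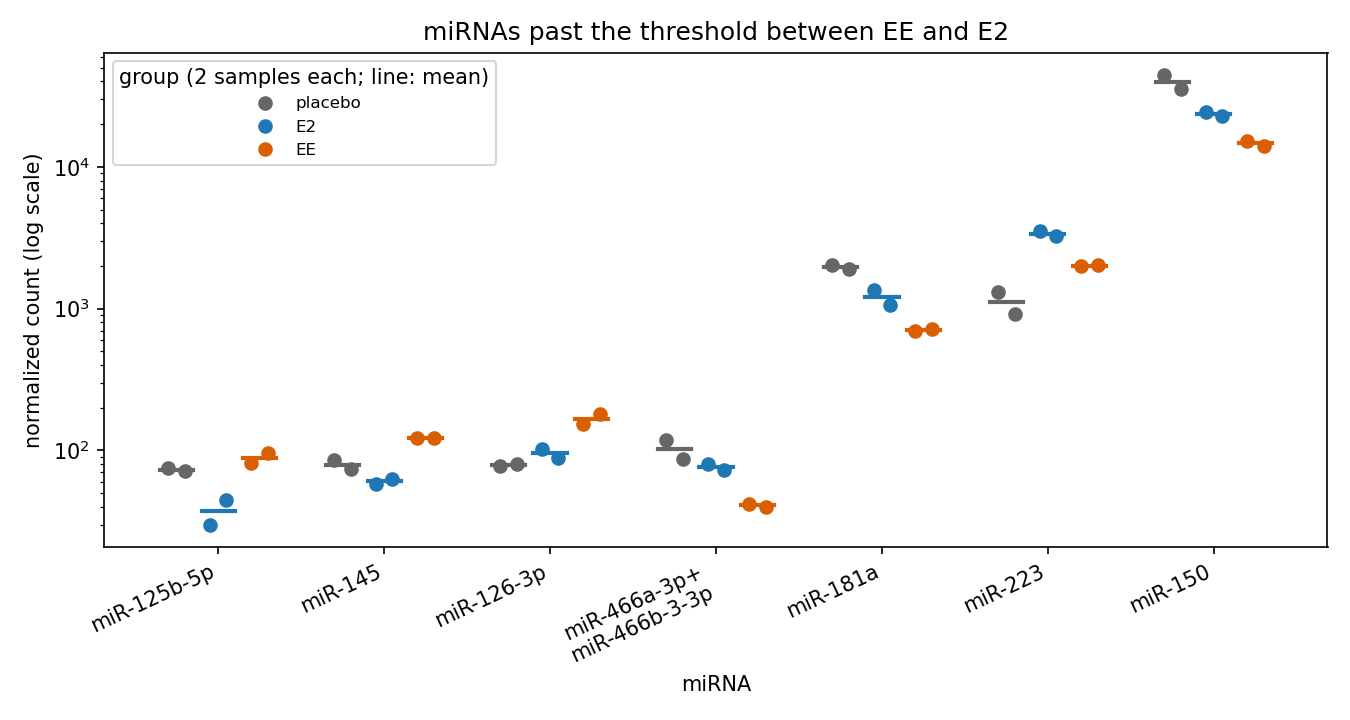
Normalized counts on a log axis of the 7 miRNAs past the threshold between EE and E2, with a point for each of the 2 samples per group and a line at the group mean. Both EE samples lie above both E2 samples for miR-125b-5p, miR-145 and miR-126-3p and below them for the other 4.

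The lymphoid list was lower with EE than with E2, with 2 of 3 members past the threshold and 3 adjusted over the list alone (median -0.67, camera adjusted p 0.00296). With quantile normalization, which removes the difference of miR-150 by construction, its median was -0.23 and it did not pass (camera adjusted p 0.205). The stromal list was higher, with 2 of 3 members in both counts (median 1.01), the earlier estrogen list of lower miRNAs was higher, with 2 of 5 in both counts (median 0.53) through the same 2 probes, miR-125b-5p and miR-145, and the Sfmbt2 cluster was lower, with 1 of 3 and 3 adjusted over the list alone (median -0.64). Camera gave each of these 3 lists an adjusted p of 0.0150. All 4 lists had an adjusted p of 0.245 with an estimated correlation, and the Sfmbt2 call ended without E2 sample 2 (adjusted p 0.121) and without EE sample 2 (0.0508). The erythroid list had no member past the threshold in either count on the deposited scale with all samples (median 0.67, camera adjusted p 0.105). Its members miR-144 and miR-451 each passed under an alternative, and whether the list passed depended on which sample was left out. The myeloid list and the earlier estrogen list of higher miRNAs each had miR-223 lower among 4, in both counts, with medians of -0.28 and 0.27 and camera adjusted p-values of 0.275 and 0.910. For the earlier estrogen list, camera pointed upward and fry downward. No member of the miR-17-92 (median 0.22), miR-29 (0.10), miR-30 (0.04) or miR-15/16 (0.01) families passed in either count, and camera adjusted p-values ran from 0.258 to 0.910. For the miR-17-92 family fry gave an adjusted p of 0.0254. The miR-15/16 mean was -0.00, and camera pointed downward. In the let-7 family (median -0.15, camera adjusted p 0.386) and the inflammatory list (median -0.03, mean 0.04, camera upward with an adjusted p of 0.604), none passed over all miRNAs, and let-7g was lower and miR-21 higher adjusted over the list alone. The medians of the other lists described here changed sign under at least 1 rescaling, while the lymphoid, erythroid, stromal and Sfmbt2 medians and that of the earlier list of lower miRNAs kept theirs. The count of 7 fell to 0 after rescaling by the median tested miRNA, without the detection filter and without E2 sample 1, and to 1 without E2 sample 2. The differences themselves were unchanged without the filter and of similar size with median rescaling, as in miR-125b-5p (1.16), miR-145 (0.93), miR-126-3p (0.71) and miR-150 (-0.76). Without E2 sample 1 these 4 were 0.96, 0.95, 0.91 and -0.63. The scaling moved the split, to 5 higher and 0 lower with housekeeping mRNAs and 0 higher and 3 lower with ligation controls, where these 4 were 1.55, 1.32, 1.11 and -0.36, and 0.74, 0.50, 0.28 and -1.20.

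A list of miRNAs reported as raised in splenocytes of lupus-prone mice had 8 probes on the panel, and 2 were tested. miR-148a was at 686 ± 45.3 normalized counts with placebo, 1096 ± 316 with E2 and 1106 ± 116 with EE (SD, n = 2 each), a rise past the threshold with EE and not with E2, over all miRNAs, while adjusted over the list alone it also passed with E2. The EE call was lost in 8 of 17 alternatives, with log2 fold changes of 0.48 to 0.79 and adjusted p-values up to 0.363, and the E2 rise passed in 2, with a robust trend and without E2 sample 2. The difference between EE and E2 was 0.04 and did not pass. miR-155 varied between samples of a group, with 111 and 204 normalized counts with placebo, 94 and 57 with E2 and 20 and 159 with EE, and it passed in no comparison on the deposited scale with all samples. Its falls passed with both estrogens with housekeeping mRNAs (-1.23 with E2 and -1.28 with EE), and without EE sample 2 it passed in all 3 pairwise comparisons, while without EE sample 1 its change with EE was 0.08. The other 6 members, miR-182, miR-183, miR-96, miR-31, miR-127 and miR-379, had means under the detection floor. In the Dlk1-Dio3 cluster 1 of 61 probes was tested, miR-376a, with log2 fold changes of 0.96 with E2 and 1.30 with EE and no call. Its sign with E2 hung on a single sample, at -0.38 without E2 sample 2, and with EE it passed in 2 alternatives, with housekeeping mRNAs (1.40) and without placebo sample 2 (2.09). The endothelial list was represented by miR-126-3p and the epithelial list by miR-200c, which differed from placebo by -0.28 with E2 and -0.19 with EE and did not pass. No probe of the skeletal and cardiac muscle list (7 probes), the pancreas list (4) or the liver list (1) reached the detection floor.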

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

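All tests of explanations in this part were chosen after the results were seen. In the direct test of EE against E2, 7 miRNAs differed between the responses to the 2 estrogens. The log2 differences, EE minus E2, were 1.25 for miR-125b-5p, 1.01 for miR-145, 0.80 for miR-126-3p, -0.67 for miR-150, -0.76 for miR-181a, -0.75 for miR-223 and -0.88 for the miR-466a-3p and miR-466b-3-3p probe. Among 511 probes outside the tests, miR-196b, a HOX-cluster miRNA, stood above the floor and above both placebo samples in both estrogen groups, with means of 68.0 (E2) and 62.0 (EE) normalized counts against 21 with placebo. miR-1839-5p did so with E2 alone, at 58.5 against 41.5, and Gapdh, a housekeeping mRNA, did so with E2 alone, at 131 against 96.0. A negative control probe reached 59 normalized counts in EE sample 1, so a level just above the floor need not exceed background. Of these 511 probes, 6 had both E2 samples and 5 had both EE samples above the floor, and 2 samples lie above both placebo samples by chance in 16.7% of cases.

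miR-144, miR-451 and miR-486 rose with both estrogens. The tables argue against scaling as the whole cause, since the smallest median log2 change over 5 other scalings was 2.47. The median SE of the 3 miRNAs was 0.34 in that setting. The top-100 rescaling among the 5 is close to the deposited scale. A single low placebo sample does not account for it either, since the smallest median without either placebo sample was 2.33. A hypothesis is that more RNA of the red-cell lineage was in the estrogen samples. The 3 log2 changes differed by at most 0.70, but their joint rise prompted the hypothesis, so this value neither supports nor excludes it, and red cells carried over at cell isolation and red-cell formation in the spleen stay open and untested.

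miR-150, miR-181a and miR-342-3p fell with both estrogens. For EE, the median log2 change closest to 0 over 5 scalings was -0.68, with quantile normalization, where the median SE of the 3 miRNAs was 0.10. That scaling sets miR-150 to 0 by construction, so the value is the change of miR-342-3p. With median rescaling, housekeeping mRNAs and ligation controls the median was -1.40, -1.32 and -1.63. The top-100 rescaling is close to the deposited scale and adds little. These values argue against scaling as the whole cause for EE. For E2 the median closest to 0 was -0.39, under ligation controls, where the median SE of the 3 miRNAs was 0.31. Scaling and a fall cannot be told apart there, for want of samples. A lower lymphoid share alone would raise markers of the other cell types alike. Erythroid and stromal medians lay at least 2.91 log2 units apart, with a spread of 0.39 that joins the median SEs of the 2 lists. The gap goes against a lower share alone, but both medians were known when it was chosen, so it is no independent test. The stromal median also rests on 3 probes, with miR-152 at 46.5 normalized counts with placebo, under the floor. A lower share together with more red-cell-lineage RNA may remain, as may lower levels per lymphocyte, and neither was tested.

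miR-125b-5p, miR-145 and miR-126-3p were higher with EE than with E2. The smallest median log2 difference over 5 scalings was 0.50, where the median SE of the 3 miRNAs was 0.32. Scaling therefore cannot be told apart from a difference with 2 samples per group. A hypothesis is that more stromal and vessel RNA was in the EE samples. The 11 other stromal and endothelial probes were all higher with EE, with a median difference of 0.25 that was 0.54 with housekeeping mRNAs and -0.23 with ligation controls, but 1 of the 11 had a mean above the floor and the negative controls were themselves 0.33 log2 units higher with EE, so these probes leave it undecided. A difference between the estrogens or their doses stays open and untested.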

How the results depend on the processing

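Every alternative was chosen before the data were examined except rescaling by housekeeping mRNAs or ligation controls and the correlation without erythroid markers and miR-223. The cause of a changed count was not tested, except that no filter tests 566 probes and the stricter filter 66, and leaving out a sample leaves fewer. DESeq2 was not run, since the values are not raw counts. No paired analysis was possible because the sample numbers in the labels differ between groups. Of 40 calls of named miRNAs, 11 held in every alternative run. They were miR-144 and miR-223 with E2, and with EE miR-142-3p, miR-144, miR-181a, miR-2132, miR-342-3p, miR-451, miR-486, miR-669a and the miR-466a-3p and miR-466b-3-3p probe. For miR-669a and that combined probe 16 alternatives were run, since the stricter filter left them out. Their EE means, 38.0 and 41.0 normalized counts, lay under the detection floor. The placebo samples of miR-144, at 73 and 45 normalized counts, lay near it. miR-150 was the most abundant miRNA in every sample, so quantile normalization sets its change to 0 by construction. None of the 40 changed sign in an alternative. Of 106 named values not past the threshold, 26 passed in at least 1 alternative, 1 of them with its sign turned, miR-15b with EE, from -0.11 to 0.12 with quantile normalization (adjusted p 0.0101). The E2 call of miR-342-3p was lost in 13 of 17 alternatives, the EE call of miR-15a in 12 of 17 and the EE against E2 call of miR-223 in 10 of 17.

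Rescaling by the median tested miRNA gave 4 miRNAs for E2 (4 higher, 0 lower), 15 for EE, 0 for EE against E2 and 13 for both estrogens (7 higher, 6 lower). At an unadjusted p under 0.05 limma gave 18 between EE and E2 before rescaling. Ligation controls gave 4 (4 higher, 0 lower), 11 (3 higher, 8 lower), 3 (0 higher, 3 lower) and 7 (4 higher, 3 lower), and housekeeping mRNAs 11 for E2, 16 for EE, 5 for EE against E2 (5 higher, 0 lower) and 14 for both estrogens. Quantile normalization moved the split to 7 higher and 5 lower for E2 and to 4 and 2 for EE against E2. The median change of all tested miRNAs between EE and E2 moved from 0.03 to 0.34 with housekeeping mRNAs and -0.49 with ligation controls, and for E2 from -0.20 to -0.41 and 0.12. Without a filter the counts were 5, 14, 0 and 11, with fold changes unchanged, and with a robust trend 13, 27, 10 and 32. The stricter filter left 2 for EE against E2, and a fit of the compared groups alone gave 12 there and 13 for both estrogens. Leaving out each sample gave 6 to 12 for E2, lowest without E2 sample 1, 15 to 23 for EE, lowest without EE sample 2, 0 to 12 for EE against E2, lowest without E2 sample 1 and highest without either placebo sample, and 14 to 21 for both estrogens, lowest without either E2 sample. A group left with 1 sample was assumed to vary like the others. Of the 40 named calls, 27 were kept without E2 sample 1, 28 without E2 sample 2, 29 and 26 without EE samples 1 and 2, and 33 and 35 without placebo samples 1 and 2.

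The correlation of the 2 responses, an r of 0.885, was 0.750 as Spearman's rho, 0.691 without a filter and 0.738 without erythroid markers and miR-223, and 0.812 to 0.901 when a sample was left out. With camera, 4 lists passed for E2, 5 for EE, 4 for EE against E2 and 4 for both estrogens, and 0 passed in each of them with an estimated correlation. The Sfmbt2 and stromal lists and the earlier list of lower miRNAs passed for E2 with fry but not with camera. For E2, fry gave 7 lists and median rescaling 2, with 2 to 4 when a sample was left out. The E2 miR-17-92 call ended in 5 of 6 such fits (kept without E2 sample 1), with the stricter filter and with median rescaling, and the lymphoid call without placebo sample 1 and with median rescaling. For EE, 3 to 5 lists passed when a sample was left out. The miR-17-92 call ended without either EE sample and the Sfmbt2 call without EE sample 2 or either placebo sample. Between EE and E2 the Sfmbt2 call ended without E2 or EE sample 2, and for both estrogens the miR-17-92 call without placebo sample 1. Quantile normalization ended all 4 lymphoid calls and the E2 miR-17-92 call. The stricter filter left 1 list for EE against E2 among 10 that could be tested, and no filter gave 7 for both estrogens. The Sfmbt2, stromal and earlier lower lists had fewer than 3 members past the stricter filter. They were not tested there, so this does not count against them. Signal over background limits the probes under 53.3 normalized counts, 471 of the 566, whose changes were not called.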

Other observations

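Some abundant miRNAs of the spleen had close means in all groups. miR-16, a ubiquitous miRNA, was at 10970 ± 108 normalized counts with placebo, 10026 ± 237 with E2 and 9813 ± 561 with EE (SD, n = 2 each). Its log2 fold change had a 95% confidence interval of -0.36 to 0.10 with E2 and -0.39 to 0.07 with EE. miR-15b was at 5174 ± 291, 5343 ± 140 and 4792 ± 86.3 (SD, n = 2 each), with intervals of -0.22 to 0.32 and -0.38 to 0.16. Neither passed the threshold in any comparison on the deposited scale, though miR-15b passed under an alternative between each pair of groups, with a change of 0.12 for EE with quantile normalization. The means of the NF-kB-induced miR-146a were further apart, at 3582 ± 31.1 normalized counts with placebo, 2894 ± 409 with E2 and 2824 ± 235 with EE (SD, n = 2 each). Its intervals were -0.65 to 0.02 with E2 and -0.68 to -0.01 with EE, and it did not pass in any comparison.

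The stromal and vessel miRNAs below the floor included miR-143, the cluster partner of miR-145, with a log2 difference between EE and E2 of 0.88 at a mean of 22 normalized counts, and miR-214, with 1.14 at 10 normalized counts. Both were chosen after their values were seen and neither was tested, and the negative controls were 0.33 log2 units higher with EE. The 33 viral miRNA probes had their highest value, 39 normalized counts, in EE sample 1, under the detection floor of 53.3. The highest negative control value, 59 normalized counts in the same sample, lay above the floor.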
